A study of Homo sapiens with 6 samples.

How the data were processed

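AGO2 HITS-CLIP was done in 22RV1 cells, an established human prostate cancer line, transfected here with a synthetic mimic of the microRNA miR-194 or with a negative control, both at 20 nM. Per the labels' protocols, cells were irradiated with ultraviolet light 24 h later, which crosslinks proteins to the RNA they touch. AGO2, the protein that carries microRNAs to their targets, was then immunoprecipitated with its RNA, and the RNA was trimmed with RNase and sequenced. The labels list 3 libraries of the mimic group and 3 of the control group. They do not say whether the libraries of a group came from separate cultures.

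The submitters' processing notes name cutadapt 1.8.1, FastQC, TopHat2 2.0.9, SAMtools, MACS2 and the genome build hg19, without the order or settings of the steps. The deposited table holds 1 score per peak, a whole number from 5 to 1270, for 7772 peaks whose names say that they were merged and called by strand. The meaning of the score is not given in the sources used here, nor is it stated whether the 6 libraries were pooled before calling. The table holds no value per library or per group and no read totals, so the depth behind a peak is unknown and binding in mimic and control cells could not be compared. No test of the mimic against the control was made. The scores are the authors' own and served only to rank and describe peaks within this list. There were 0 columns of other samples.

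The table also gives each peak's place on hg19, the RefSeq transcript and the part of the gene it lies in, a gene name, and matches to a target site pattern with their bases and strand. The search that listed these sites is not described in the sources used here. Each listed site was classed by its bases against the seed of miR-194-5p: an 8mer (CTGTTACA), a 7mer-m8 (CTGTTAC), a 7mer-A1 (TGTTACA), a 6mer (TGTTAC), or a variant when the 6mer was absent. A 7mer match below means any of the first 3 classes. Of 1577 sites listed on the peak's own strand, 1346 (85.4%) held the 6mer. The listed pattern differed between parts of the gene. Counting from 1 at the 5' end of the listed bases, 3' UTR sites had 10 bases with the 6mer from place 4, sites in coding exons and most other classes had 9 bases with the 6mer from place 3, and intron sites and 5 of the 7 wrong-strand sites that hold a 6mer had 9 bases with the 6mer from place 2. Shares of peaks with a match are therefore not directly comparable between these parts. Of 3659 gene names, 3512 were current symbols, 132 older symbols, and 15 matched neither. Dates stood in place of symbols in 9 annotation texts, while the gene name column was intact.

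Flanking windows on hg19 had been planned as the background for seed matches, but no hg19 sequence was used here. Matches on the opposite strand of the same peaks served instead. The split between strands was compared by an exact binomial test with the split in the windows described next, which was not 1 to 1. A second background was every window of the peak's length in the same 3' UTR or coding sequence, from GENCODE 29 transcripts matched by RefSeq accession. These windows include the peak itself, so a site in the peak can also count in its background. The chance of a match per peak was summed and the observed number was compared with it by an exact Poisson-binomial test, with 1000 bootstrap draws over genes for the interval. Both backgrounds were chosen after seeing the data, as were the within-gene and site-position tests. No GENCODE coordinate was compared with an hg19 coordinate.

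Differences in log2 score were tested by permutation (100000 resamples), and differences within a gene by random sign changes of each gene's value. The place of sites in peaks was compared with even placement in 10000 draws. Shares were compared by Fisher's exact test and have exact Clopper-Pearson 95% intervals, which cover counting error only. All tests were two-sided, and Benjamini-Hochberg adjustment was applied within each family with a threshold of 0.05. Peaks of 1 gene are not independent, and the p-values across peaks describe this list, not the spread between cultures. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

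The tests were checked on simulated data. With 7772 simulated peaks the score test called 100% of sets made with a 1.1-fold difference and 5% of those with none. With 190 simulated genes the within-gene test called 55% of sets at 1.25-fold and 100% at 1.5-fold. With 1714 simulated 3' UTR windows the window test called 97.5% of sets at 1.5-fold and 0% of those with none. For the score test, scores and matches were shuffled over all peaks, and the windows were drawn evenly. The clustering of real peaks was therefore absent, and the rate of false calls on this list was not measured.

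Before the data were examined, 11 gene lists and the rule for named genes were fixed. The lists were reported miR-194 targets, androgen signalling, luminal epithelial identity, neuroendocrine and neuronal identity, RB and E2F cell cycle, the miRNA pathway, chromatin regulators, PI3K, RAS and receptor kinase signalling, WNT, TGF-beta and mesenchymal genes, abundant housekeeping transcripts, and markers of cells foreign to an epithelial line. The rule takes the 12 genes with the highest peaks, the 12 genes with the highest 3' UTR peaks that hold a 7mer match, and up to 4 members per list by the score of their highest peak with a 7mer match. Some genes that the rule takes are not reported here. Any other gene was named after its values were seen. Alternatives varied the seed type, the part of the gene, the score range, the peak length, the joining of peaks within 50 nt, the transcript, and the counting of 1 peak per gene.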

Results

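The data were 7772 AGO2-crosslinked RNA regions (peaks) from a study of 22RV1 prostate cancer cells that received a miR-194 mimic (3 libraries) or a negative control (3 libraries). The series asks which transcripts miR-194 binds in these cells. The table is 1 list of merged peaks with 1 score per peak. Which of the libraries entered it is not stated, and the depth per library is unknown. Peaks gained or lost with the mimic could therefore not be identified, and each value below describes this list, with no replicate behind it. The peaks had a median length of 67 nt (interquartile range 49 to 92) and a median score of 15 (12 to 23), with 3873 on the plus and 3899 on the minus strand.

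AGO2 peaks lay mostly in coding exons, 3' UTRs and introns. Coding exons held 2567 peaks (33.0%), 3' UTRs held 1791 (23.0%, 95% interval 22.1 to 24.0%) and introns held 1585 (20.4%). Among the smaller classes, 425 peaks lay at promoters and transcription starts, 417 at transcript ends, 259 in non-coding transcripts and 116 in 5' UTRs. Coding exon and 3' UTR peaks both had a median score of 17, against 13 for intron peaks. A gene name was given for 7117 peaks, from 3659 genes. Of these genes, 2040 had 1 peak and 239 had at least 5. STEAP2, a metalloreductase of prostate epithelium, had the most with 25 peaks, 23 of them in its 3' UTR. DYNC1H1, the dynein heavy chain, had 19, and SPTBN1 (a spectrin) and THBS1 (thrombospondin) had 15 each.

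The highest score, 1270, belonged to RPL9, a protein of the large ribosomal subunit. Its single peak covered chromosome 4, 39459207 to 39459301 (hg19, minus strand), in exon 3 of 7, and held a 7mer-A1 match. Of the 12 genes with the highest peaks, 5 had a 7mer match in that peak. Besides RPL9 these were FAM118B (score 945, at a transcript end), ZBTB10 (756, 3' UTR), the calcineurin-like protein gene CHP1 (566, coding exon 5 of 7) and ERGIC2, of the endoplasmic reticulum to Golgi pathway (559, 3' UTR). The FAM118B peak was on the minus strand and carries the authors' gene name. Whether that gene lies on the same strand was not checked, so the peak may belong to another transcript. Another 4 held only a variant site: TM9SF3 (950), the cation-transporting ATPase gene ATP13A3 (846), the amino acid transporter gene SLC38A2 (745) and the mitochondrial phosphate carrier gene SLC25A3 (636). No site was listed in the highest peaks of the actin-binding gene TAGLN2 (721), REEP5 (699) and the RNA helicase gene DHX9 (589).

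Matches to the miR-194 seed were common in the peaks and lay almost entirely on the transcribed strand. A 7mer match was listed in 1038 peaks (13.4%, 95% interval 12.6 to 14.1%), and its reverse complement in 29 (0.373%, 0.250 to 0.535%). There were 1034 peaks with a match on the transcribed strand alone and 25 with one on the opposite strand alone (97.6% on the transcribed strand). Windows of the matched 3' UTRs and coding sequences also held the 7mers more often than their reverse complement, 3.70 times in 3' UTRs and 4.29 times in coding exons. These windows include the peaks, so the peaks' own sites may account for part of this excess. The share of 97.6%, over peaks of all classes, lay above the 81.1% of the coding windows, the higher of both (exact binomial p = 2.60e-62). No windows were made for the other classes. In 3' UTR peaks alone 97.0% were on the transcribed strand, also above 81.1% (exact binomial p = 7.32e-20). The share of peaks with a 7mer match was 19.8% in 3' UTR peaks, 15.0% in coding exon peaks and 20.4% at transcript ends. It was 20.5% in non-coding transcripts and 4.61% in introns. Listed patterns differed between 3' UTRs, introns and most other classes. At least 1 peak with a 7mer match was present in 862 of the 3659 genes (23.6%, 22.19 to 24.97%), and in 3' UTR peaks of 322 of 910 genes (35.4%, 32.3 to 38.6%). With 8mer matches alone the share of peaks was 4.16%, and among the 3465 peaks above the median score it was 23.9% for 7mers.

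Peaks held 7mer matches several times as often as windows drawn from the same 3' UTR or coding sequence. In 3' UTRs, 335 of 1714 peaks with a matched transcript held one (19.5%), where windows of equal length in the same 3' UTRs would give 63.2 (3.69%), a ratio of 5.30 (95% interval 4.61 to 6.16, exact p = 2.92e-174). In coding exons, 379 of 2533 peaks held one (15.0%) against 50.7 (2.00%), a ratio of 7.48 (6.62 to 8.52, exact p = 1.53e-251). The coding ratio was 1.41 times the 3' UTR ratio (1.15 to 1.70), but sites of the 2 classes were listed by different patterns, which limits this comparison. The windows also include the peaks' own sites, with a weight that depends on the length of the sequence. The reverse complement of the 7mers was found in 14 3' UTR peaks against 17.1 in such windows (exact p = 0.525) and in 9 coding exon peaks against 11.8 (exact p = 0.505). The GENCODE transcripts differ in part from those of the table: 85.8% of the listed 3' UTR sites and 99.0% of the coding sites were found in the matched sequence.

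**Figure D1:**
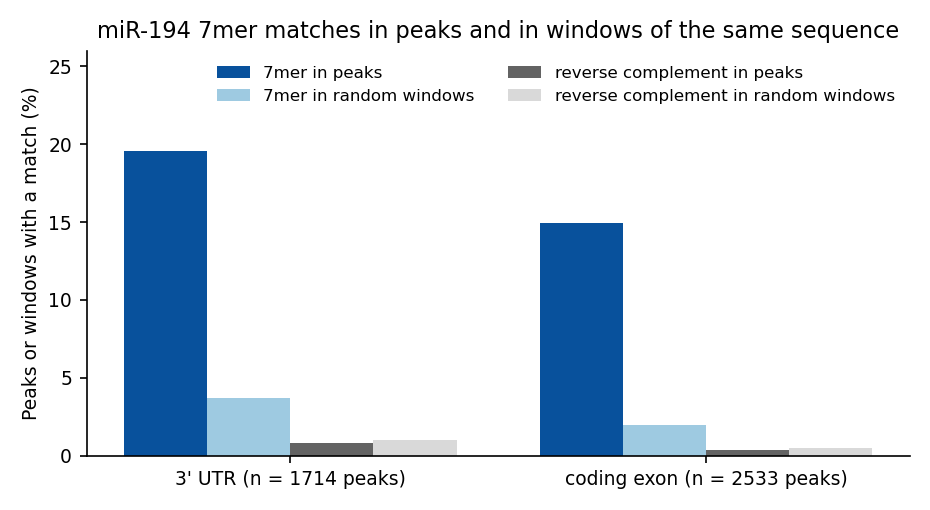
Share of peaks with a miR-194 7mer match or with its reverse complement (vertical axis, percent), in 3' UTR and coding exon peaks, beside the share in all windows of equal length in the same sequences. The 7mer share in peaks was 19.5% in 3' UTRs and 15.0% in coding exons, above the 3.69% and 2.00% of the windows, while the reverse complement stayed near its window share.

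Listed matches were more often in 3' UTRs than the other peaks were. Of the 1038 peaks with a 7mer match 354 lay in 3' UTRs (34.1%), against 1437 of 6734 peaks without one (21.3%; odds ratio 1.91, Fisher's exact p = 2.49e-18). Without intron peaks the odds ratio was 1.53. Because 3' UTR sites were listed by another pattern than those of coding exons, part of this difference could not be separated from the site search.

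Every class of miR-194 site went with higher scores than no site. The median score was 30 (interquartile range 18 to 66.5, 323 peaks) for 8mers, 32 (17 to 72, 295 peaks) for 7mer-m8, 30.5 (18 to 63, 420 peaks) for 7mer-A1, 32 (18 to 56, 267 peaks) for 6mers and 27 (15 to 47, 204 peaks) for variant sites. It was 14 (12 to 18) for the 6263 peaks without a site and 15 (12 to 17) for the 25 peaks with a 7mer on the opposite strand only. On a geometric mean scale the classes lay 2.05-fold (variant) to 2.42-fold (7mer-m8) above peaks without a site, each with a permutation p of 1e-05, the smallest that the permutations can give. Differences between classes were smaller. Over all peaks these comparisons mix parts of the gene, and intron sites were listed by another pattern. Intron peaks, with a median score of 13, made up 44 of the 323 8mer peaks, which limits the comparisons over all peaks. None of 14 comparisons between classes, over all peaks and in 3' UTRs, passed the adjusted threshold, and 2 had an unadjusted p under 0.05. In 3' UTRs, 7mer-m8 peaks scored 1.36 times as high as 6mer peaks (permutation p = 0.0223, adjusted p = 0.260), and 1.27 times as high as 7mer-A1 peaks (permutation p = 0.0387, adjusted p = 0.260).

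**Figure D2:**
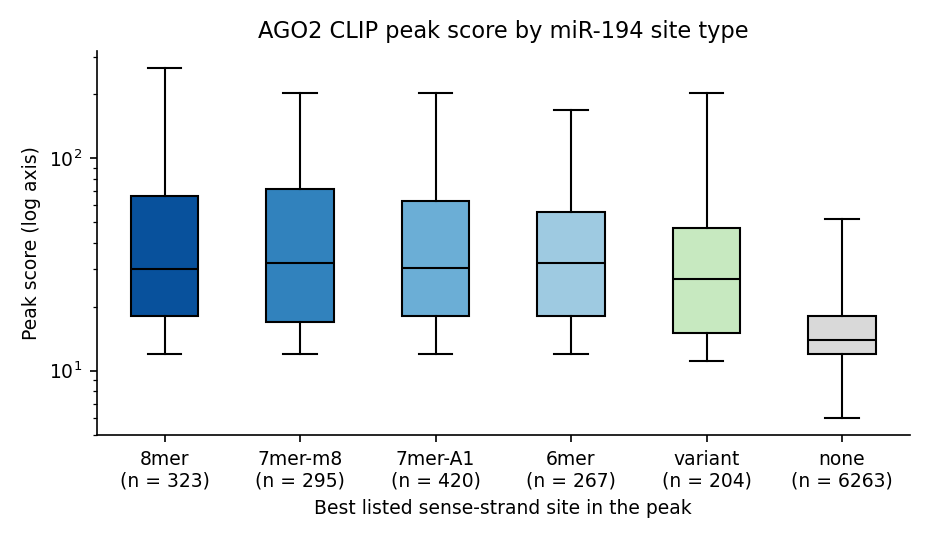
Peak score (vertical log axis) by the best miR-194 site listed on the peak's own strand, with the number of peaks (n) under each class. Boxes give the quartiles and median and whiskers the 5th and 95th percentiles; the medians lie between 27 and 32 in the classes with a site and at 14 without one.

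Across peaks, which are not independent replicates, the score rose with having a 7mer match (Spearman's rho 0.327, Pearson's r 0.362 on log2 scores, permutation p = 1e-05, the smallest possible). Of the 2056 peaks scoring at least 23, 663 (32.2%) held a 7mer match, against 97 of the 2398 peaks scoring at most 12 (4.05%; odds ratio 11.3, Fisher's exact p = 7.39e-148). Peaks with a match were longer, with a median of 92 nt against 63 nt, and rho was 0.245 when peaks were compared within 10 strata of length. The odds ratio was not adjusted for length.

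The higher score held among 3' UTR peaks of the same gene. In 190 genes with both kinds of 3' UTR peak, those with a 7mer match exceeded the others by 1.61 ± 0.10 (SE) on the log2 scale, or 3.06-fold (95% interval 2.67 to 3.49). The match side was higher in 161 genes and lower in 25 (sign-change permutation p = 1e-05, the smallest possible). In THBS1, a secreted matrix glycoprotein, the 3' UTR peak with an 8mer (chromosome 15, 39887968 to 39888389, plus strand, exon 22 of 22) scored 478, and the other 7 scored 10 to 213. In CUL4B, a ubiquitin ligase scaffold, the 3' UTR peaks with a match scored 250, 62 and 19 and those without scored 9, 6 and 6. PMEPA1, an androgen-induced gene, went the other way for its highest peaks: its 7mer-m8 peak scored 55 and another 3' UTR peak scored 165. With scores adjusted for peak length the difference was 2.19-fold. With only peaks scoring at least 12 kept, it was 2.38-fold (2.06 to 2.76) in 141 genes. Low-scoring peaks beside a higher one, such as those scoring 6 in CUL4B, may thus widen the 3.06-fold difference.

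**Figure D3:**
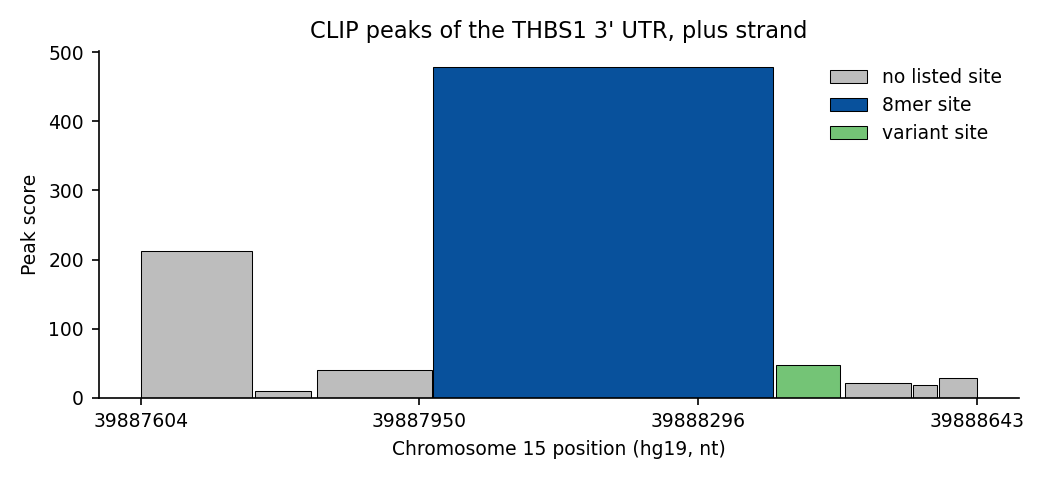
Peaks of the THBS1 3' UTR on chromosome 15 (hg19, horizontal axis in nt), each drawn as a bar over its start and end with its score as height (vertical axis). The 422 nt peak that holds the 8mer, the longest of the whole list, scored 478, and the next highest, without a listed site, scored 213.

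Sites lay near the middle of their peaks. The 1064 7mer sites were 15.3 ± 14.0 nt (SD) from the peak centre, with a median of 11 nt and 71.5% within 20 nt, whereas even placement along the same peaks gave a mean of 23.4 nt (22.5 to 24.3, permutation p = 0.0001, the smallest possible). The 29 sites on the opposite strand were farther out than even placement gives, 25.5 nt against 19.8 nt (15.2 to 24.5, permutation p = 0.0138).

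**Figure D4:**
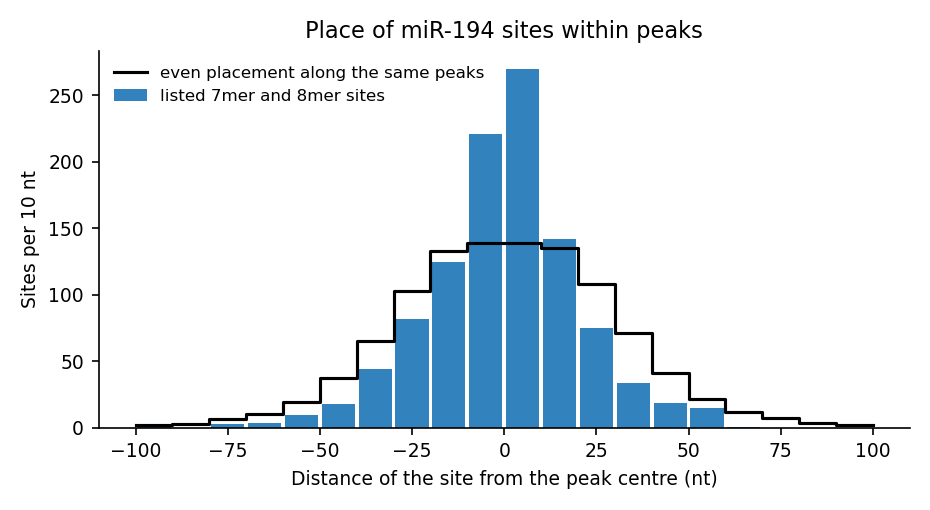
Number of listed 7mer and 8mer sites per 10 nt (vertical axis) by distance from the peak centre in nt (horizontal axis), with the number that even placement in the same peaks would give as a line. The bins next to the centre hold 221 and 270 sites against 139 under even placement.

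The highest 3' UTR peaks with a 7mer match belonged to genes of varied function. After ZBTB10 (756; chromosome 8, 81432587 to 81432712) and ERGIC2 (559; chromosome 12, 29493754 to 29493954), the order was SYT4, a synaptotagmin (551, 8mer; chromosome 18, 40848081 to 40848217), THBS1 (478), sulfite oxidase SUOX (390, 8mer), the retinol dehydrogenase gene RDH11 (386, 7mer-m8), the lysosomal membrane gene LAMP2 (312, 8mer) and the ephrin receptor gene EPHA3 (310, 7mer-A1). SPCS3, of the signal peptidase complex, followed with 305, then the planar polarity gene VANGL1 with 297, and MAGT1 and TMEM209 with 267 each. Of these 12 genes, 7 had an 8mer in the named peak.

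Among 23 genes listed as reported miR-194 targets, 14 had a peak and 8 of these had a 7mer match in one (57.1%), against 854 of 3645 other genes (23.4%; odds ratio 4.36, Fisher's exact p = 0.00695, adjusted p = 0.0695 over 10 lists). The members with a match include THBS1 (478), CUL4B (250), the small GTPase gene RAC1 (128) and the phosphatase gene PTPN13 (40). FOXA1, a pioneer factor of luminal cells that is on this list and was singled out after its values were seen, had 5 3' UTR peaks between 38059333 and 38059931 on chromosome 14 (minus strand). Their scores were 250, 96, 53, 46 and 12, no 7mer was listed in any of them, and 1 held a variant site (GAAAGTTACA). The GENCODE 3' UTR of FOXA1 (1384 nt) does hold a miR-194 7mer at 1 place, which is not among the sites listed in these peaks. Over the other settings the adjusted p was 0.574 among peaks above the median score and 0.236 in 3' UTR peaks. The list was drawn from general knowledge, and entries first reported from these cells would not be independent of them.

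No list passed the adjusted threshold by Fisher's exact test, and only the reported targets had an unadjusted p under 0.05. Of 20 genes of the androgen signalling list 8 had a peak and 4 a 7mer match (exact test, adjusted p = 0.294). Those with a match included STEAP2 (185, 7mer-A1) and PMEPA1 (55, 7mer-m8), both in the 3' UTR. Of 18 luminal genes 5 had a peak and only GRHL2, an epithelial transcription factor, had a match (157, 8mer, 3' UTR; exact test, adjusted p = 1). Of 26 neuroendocrine and neuronal genes 6 had a peak and 3 a match (exact test, adjusted p = 0.294): ONECUT2, a transcription factor of neuroendocrine prostate cancer (233, 8mer), the retrotransposon-derived gene PEG10 (88, 8mer) and DPYSL3 (25, 7mer-m8).

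Chromatin regulators had peaks in 20 of 35 genes and a match in 8 (exact test, adjusted p = 0.294), among them the methyltransferase gene KMT2A (184), the demethylase gene KDM5A (112), the deacetylase gene HDAC2 (78) and ARID2, of a SWI/SNF complex (54, with a match in 5 of its 7 peaks). In PI3K, RAS and receptor kinase signalling 11 of 28 genes had a peak and 3 a match (exact test, adjusted p = 0.910), among them the insulin receptor gene INSR (83) and IGF1R (35). In the WNT, TGF-beta and mesenchymal list 6 of 22 genes had a peak and 3 a match (exact test, adjusted p = 0.294), FZD6 (34), LRP6 (15) and SKI (12). Genes of the miRNA pathway had peaks in 10 of 23 and a match in 3 (exact test, adjusted p = 0.910), HELZ (26), CNOT6 (25) and AGO1 (21). In the RB and E2F list 5 of 22 genes had a peak and CDK6 alone a match (12, 7mer-m8; exact test, adjusted p = 1). Abundant housekeeping genes had peaks in 8 of 25, with no match (exact test, adjusted p = 0.352), although the heat shock gene HSPA8 reached a score of 548. None of 16 markers of blood, vessel, stromal and other foreign cells had a peak. A gene without a peak was not necessarily unexpressed, and these tests do not allow for the number of peaks per gene.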

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

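The low-score test on neighbouring peaks and the test at MIR194-1 were chosen after their results were seen.

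Peaks with a miR-194 7mer match scored 2.26-fold higher than the rest, and 3 technical explanations were set against this. Length as the whole cause is argued against by a log2 difference of 0.877 that remained within 10 strata of peak length. The gap was uneven across the strata. Median scores with and without a match were 14 and 13 at 38 to 45 nt, and 65 and 22 at 123 to 422 nt. In the shortest stratum, up to 37 nt, they were 21 and 12, with only 7 matched peaks. The longest stratum is wide, so length was not held fixed within it. Abundance at the level of the gene is argued against by the difference of 1.612 between 3' UTR peaks of the same gene. The abundance of single transcripts is not covered, since 3' UTR peaks of a gene can be assigned to different transcripts, as in STEAP2. A site search that favoured high peaks whatever the strand is argued against by the gap of 1.156 (permutation p = 4e-05) between peaks with the match on their own strand and peaks with it on the opposite strand only. The opposite-strand peaks were shorter (median 65 nt against 92 nt) and only 25 in number. The gap was not adjusted for length, which limits this reading. Loading of AGO2 with the mimic is a candidate explanation that stays open as a hypothesis, because no value separates mimic from control cells, and so does binding by the cells' own miR-194.

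The table lists a peak at MIR194-1 itself, with a score of 23, on chromosome 1 from 220291545 to 220291572 (minus strand, 28 nt). It is 1 of the 25 peaks with a 7mer on the opposite strand only. Its listed bases, TGTAACAGC, match the 5' end of mature miR-194-5p at all 9 places, but a reverse-complement 8mer at this gene fixes that match in advance. Whether the peak holds reads of the mature microRNA or the mimic therefore stays open. The same bases are listed in a coding exon peak of PPP1R13B (score 16), and no biological explanation was tested.

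Some peaks entered the comparisons over all peaks but not those by part of the gene. The highest of 4 peaks named for MIR4485 scored 536, on chromosome 11 from 10529882 to 10529982, without a miR-194 site. There were 401 intergenic peaks, 12.2% of them with a 7mer match, and the highest scored 502 on chromosome 15 from 25237191 to 25237286, with a 7mer-A1 match. Another 210 peaks lay on the wrong strand of an annotated gene, 3.33% of them with a 7mer match. Distances to a site were filled in for 1915 peaks that list no site, each within 1 nt of 5 minus the distance from the peak's start to its centre, and were not used.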

How the results depend on the processing

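The windows and the strand test against them, the within-gene, site-position, joined-peak and length-strata settings, the 8mer setting of the 3' UTR odds ratio, and those without intron peaks were chosen after seeing the data. For the main comparisons, 43 alternative values kept their direction and their side of the threshold (or stayed within 1.5 times for counts) and 2 moved beyond their interval. The 3' UTR share of 23.0% was 28.5% among peaks above the median score and 24.9% when genes were counted. The share of peaks with a 7mer match ranged from 4.16% (8mers) to 23.9% (peaks above the median score), and the share of matches on the transcribed strand exceeded that of the windows each time (largest exact binomial p = 1.08e-14). The ratio to windows ranged from 4.58 to 7.92 in 3' UTRs and from 6.80 to 10.3 in coding exons. Spearman's rho ranged from 0.245 to 0.376, the odds ratio of high against low scores from 10.8 to 13.4, and the within-gene log2 difference from 1.13 to 1.63. The odds ratio was not adjusted for peak length in any setting. Among list counts 13 alternatives fell by over 1.5 times, since fewer peaks entered, and 7 did not. No paired analysis was possible because the table holds no column per replicate or group. For the same reason no alternative for binding in mimic against control cells was run, nor were replicates left out. Flanks, shuffled peak sequences and the rank of the seed among 7mers of the same composition were not run because no hg19 sequence was used here, and the table gives no second rank column. Unknown depth limits how firmly any score can be read.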

Other observations

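Several coding sequences carried repeated miR-194 matches. ARID2 had 7mer matches in 5 of 7 peaks, 4 of the peaks being in coding exons. TNKS2, a tankyrase, had 4 in 12 peaks, 11 of them coding, with a top score of 368. The spindle gene ASPM had 3 in 8 coding peaks (top score 130), the condensin gene NCAPD3 3 in 5 coding peaks (213) and the copper transporter gene ATP7A 3 in 4 coding peaks (55). Other genes had many peaks and no 6mer listed in any of them. The neuronal pentraxin receptor gene NPTXR had 9 peaks, all in its 3' UTR, with a top score of 36, and EDEM3 had 9, 6 of them in the 3' UTR (57). FKBP5, an androgen-induced chaperone, had 8 peaks with a top score of 69. These genes were chosen after their values were seen.

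Intron peaks had a median score of 13, and a few stood far above it. The highest belonged to FNBP1 (187, with an 8mer), followed by CLCC1 (105), DDB1 (88) and UBA1 (82), none of which had a listed site in that peak apart from FNBP1. These genes were also chosen after their values were seen.

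Low scores clustered near other peaks. The 1386 peaks scoring under 12 lay within 50 nt of another peak in 79.9% of cases, against 34.9% of the others, a ratio of 2.288. This is consistent with pieces of 1 enriched region split in peak calling, a test chosen after the result was seen. Short length as the cause is argued against by a ratio of 2.642 among peaks of 40 to 80 nt (75.3% against 28.5%). No biological explanation was tested.

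A hypothesis that some gene family holds miR-194 sites more often than the rest of the table was tested on 16 families. The number with an adjusted p under 0.05 was 0, and 0 had an unadjusted p under 0.05 (Fisher's exact test). RAB genes had a 7mer match in 6 of 15 genes (40.0%, exact test, adjusted p = 0.771), ubiquitin peptidase genes in 7 of 18 (38.9%, adjusted p = 0.771) and ZNF genes in 11 of 71 (15.5%, adjusted p = 0.771), against 23.5 to 23.7% of the other genes.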
